A study of Mus musculus with 9 samples.

How the data were processed

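RNA was measured by bulk sequencing of dissected cortex from mice at postnatal day 0, in 9 libraries: 3 from wild-type littermates, 3 from mice labelled ShhN IUE and 3 from mice carrying hGFAP-Cre and a conditional SmoM2 allele. Groups and replicate numbers were taken from the sample titles. The labels call the wild-type animals littermates but do not say whether the replicates of a group came from separate animals or litters, so p-values measure the spread between these samples.

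The authors deposited 2 tables, one for ShhN IUE with wild type and one for SmoM2 with wild type, and the same 3 wild-type libraries appear in both. Per the file headers, each table gives for every gene and library a read count and an FPKM value, and a p-value and q-value for the authors' own comparison. The submitters' processing notes name HISAT2, StringTie and edgeR and the builds GRCm38.p4 and mm10, with no versions. How reads shared between gene copies were assigned, and whether strand was used, is not given in the sources used here. FPKM values were used only to check the tables. Coordinates are those of the deposited tables.

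The wild-type libraries were quantified differently in the 2 tables. Over 22268 genes present in both, 30.5% had identical counts in all 3 wild-type libraries. Of 16228 genes with at least 60 wild-type counts over both tables, 4208 (25.9%) differed by more than 0.1 on the log2 scale between tables, and 251 differed by more than 1. The mitochondrial gene mt-Co1 had 538950 wild-type counts in one table and 1 in the other. Each comparison with wild type was therefore tested within its own table. A gene's wild-type counts are said below to agree when the log2 ratio of its summed wild-type counts, each with 5 added, lay within 0.1 of 0, a tolerance chosen after the data were examined.

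Counts were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, TMM scaling and its default expression filter by group. Adjusted p is by the Benjamini-Hochberg method, with a threshold of 0.05, and SE was derived from the log2 fold change and the F statistic. Mean and SD are of TMM-scaled values per 1e+06 counts (CPM). The comparison of SmoM2 with ShhN IUE departs from the design fixed before the data were examined. That design allowed a joint fit only if the wild-type counts of the tables agreed, and otherwise values side by side. They agreed for 16195 genes and not for the rest, so all 9 libraries were fitted over those genes, with wild-type counts averaged over the tables, and other genes were not tested. CPM in that fit are relative to those genes, and are higher than in the other fits.

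The 26 gene lists, the tests and the rule for named genes were written before the data were examined. Lists were tested with camera of limma 3.58.1, two-sided, at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, and again with a correlation estimated from the data, and with fry. Genes past the threshold were eligible for naming with a mean of at least 5 CPM and no overlap between groups. Mitochondrial genes (mt-), Rn45s and predicted or clone-derived names were left out. Named genes are the 8 largest rises and the 8 largest falls among the eligible genes. They also include up to 4 members of each list with the smallest adjusted p, of which the text leaves some out, and a fixed set always named, of which 2 genes are not reported here: Shh, Smo, Gli1, Gli2, Gli3, Ptch1, Hhip, Egfr, Olig2, Gsx2, Dlx2, Eomes, Pax6, Pdgfra, Gfap and Bcl11b. Groups of 3 against 3 fall apart without overlap in 10% of genes by chance. Gene Ontology terms of the deposited tables with 15 to 300 tested genes were tested with a one-sided Fisher's exact test against all tested genes that carry a term.

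Alternatives were RLE or upper quartile scaling, no filter or a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, a 2-fold minimum, and other sets of libraries in the fit. Restriction to genes with agreeing wild-type counts, and tolerances of 0.05 and 0.2, were added after the data were examined.

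The functions were tested on simulated counts with 200 genes changed by known folds. For ShhN IUE against wild type, over 15972 genes, edgeR recovered 46.5% of 2-fold and 81.0% of 4-fold changes, and 11.2% of its calls were false, above the nominal 5%. For SmoM2 against wild type, over 16258 genes, it recovered 57.1% and 99.0%, with 6.7% of calls false. For SmoM2 against ShhN IUE, over 12159 genes, it recovered 51.0% and 91.0%, with 3.4% of calls false. DESeq2 gave 19.8%, 18.4% and 14.3% false calls in these simulations, and limma-voom 10.6%, 6.2% and 2.1%. Each simulation was drawn once. Of 24 simulated unchanged lists, 0 were called by camera in each comparison, and both changed lists were.

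Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom of 16.5 to 34.3 over genes, so none was treated as a library deposited more than once. Intervals given for low counts are 95% and cover counting error only, and those of a ratio of spreads come from 2000 resamplings of genes.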

Results

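The cortex of newborn mice was profiled in 3 groups of 3 libraries. ShhN IUE denotes in utero electroporation of ShhN, the amino-terminal signalling part of Sonic hedgehog (SHH). SmoM2 is an activated form of Smoothened, the SHH signal transducer, switched on here by Cre under the human GFAP promoter. Totals were 15376071 to 19604672 counts in the ShhN IUE libraries, 23625702 to 26923127 in the SmoM2 libraries and 18610507 to 21694348 in the wild-type libraries. The comparisons ask, after the title of the series, what raised SHH signalling does to the progenitors of the cortex and their progeny. No group is labelled as electroporated without ShhN. In every comparison with ShhN IUE, effects of the electroporation itself cannot be told apart from those of ShhN. Any difference between the groups in genetic background, litter or batch would also move with the group. In every comparison it could not be told apart from an effect of the intervention.

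The genes that the interventions concern were examined in every library first. Shh had 51, 52 and 455 counts in ShhN IUE libraries 1, 2 and 3, and 36, 62 and 31 in wild-type libraries 1, 2 and 3. The log2 fold change of Shh in ShhN IUE was 2.40 ± 0.89 (SE, n = 3 per group), and it did not pass the edgeR test (adjusted p = 0.0693). In SmoM2 libraries Shh had 5, 15 and 9 counts and fell by 2.47 on the log2 scale (SE 0.44, adjusted p = 0.00697), a call lost in a fit of all 9 libraries (adjusted p = 0.0960). Smo rose 3.59-fold in SmoM2, from 21.9 ± 3.71 to 78.7 ± 6.36 CPM (mean and SD, n = 3), and 1.89-fold in ShhN IUE. Counts of Shh and Smo may include reads of the introduced ShhN and SmoM2 sequences, which was not tested.

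**Figure D1:**
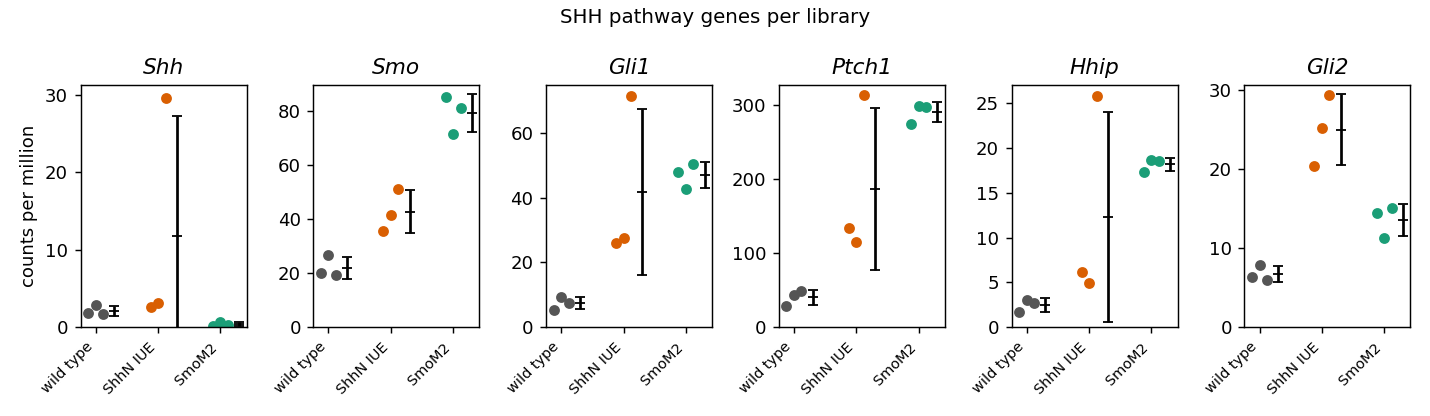
CPM of the library total, without TMM scaling, for 6 SHH pathway genes in the 3 wild-type, 3 ShhN IUE and 3 SmoM2 libraries; points are libraries, and the bar beside them is the mean with its SD, which for Shh in ShhN IUE reaches below the axis. ShhN IUE library 3 holds 455 of the counts of Shh, against 51 and 52 in the other ShhN IUE libraries, and is also the highest ShhN IUE library for Gli1, Ptch1 and Hhip.

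In ShhN IUE against wild-type cortex, 27 of 30 cell cycle genes, 13 of 24 genes of the olfactory bulb interneuron lineage and 7 of 18 SHH pathway targets rose, and 17 of 18 genes of striatal projection neurons fell. The lists other than the SHH targets passed camera at its preset correlation, and none did with an estimated correlation (lowest adjusted p = 0.370). Gli1, a transcription factor induced by the pathway, rose 5.42-fold, from 7.51 ± 1.75 to 40.9 ± 24.3 CPM (SD, n = 3), and Ptch1, the SHH receptor, rose 4.50-fold, from 40.7 ± 10.2 to 183 ± 103 CPM. The log2 fold change of Gli1 was 1.84 without ShhN IUE library 3, against 2.44 with all libraries. Sp8, a transcription factor of olfactory bulb interneurons, rose 7.74-fold, and Dlx2 rose 2.89-fold. Tac1, a striatal gene that encodes substance P, fell from 10.8 ± 1.13 to 0.371 ± 0.168 CPM. Among 16180 genes tested, 2602 rose and 2778 fell (edgeR quasi-likelihood test).

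The 8 largest rises by the naming rule were Zbtb20 (log2 fold change 5.14), Rps12-ps3 (3.62), Slc16a3 (3.02), Crocc2 (2.95), Sp8 (2.95), Itih3 (2.95), Pipox (2.79) and Zfp422 (2.79). Zbtb20 (chromosome 16, 42875881 to 43642602) had 325 wild-type counts in this table and 660 in the other, and Zfp422 had 792 and 1616, so their folds depend on how the reads were counted. Rps12-ps3 is a pseudogene, and its counts are uncertain where reads match the parent gene. Crocc2 lost its call without ShhN IUE library 1 or wild-type library 1 or 3, with limma-voom and with the replicate block, with adjusted p up to 0.0646 over its alternatives. Its log2 fold change was 2.22 without ShhN IUE library 1, and without ShhN IUE library 3 that of Slc16a3 was 2.44 and that of Itih3 1.93. The 8 largest falls were Tac1 (-4.86), the pseudogene Rpl10-ps3 (-4.65), Nexn (-4.24), Ebf1 (-3.97), Rasgrp1 (-3.91), Cyp26b1 (-3.89), Col25a1 (-3.76) and Strip2 (-3.76). Tac1 lies on chromosome 6 from 7554879 to 7565834.

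Of 18 SHH pathway targets, 7 rose, among them Gli2 (log2 fold change 1.85 ± 0.18, SE) and Ccnd2 (1.65 ± 0.13), and 11 did not pass. Adjusted over the list alone 8 rose and 2 fell, and the list as a set did not pass camera (adjusted p = 0.133). Hhip rose 4.74-fold (adjusted p = 0.0259) but lost the call without wild-type library 1, 2 or 3 in turn and with limma-voom (adjusted p up to 0.0837). Its log2 fold change of 2.25 was 1.15 without ShhN IUE library 3. Of the targets 2 fell without ShhN IUE library 2. Of 15 pathway components tested 5 rose (9 adjusted over the list alone), with camera adjusted p = 0.00506 and adjusted p = 0.394 with an estimated correlation. Gli3 changed by 0.18 ± 0.15 on the log2 scale (adjusted p = 0.382).

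Of 30 cell cycle genes 27 rose and 3 did not pass, with a median log2 fold change of 1.32. Mki67 rose by 1.74 ± 0.14 and Bub1b by 2.05 ± 0.20 on the log2 scale. Adjusted over the list alone 28 rose. The camera adjusted p was 2.23e-14, and adjusted p = 0.370 with an estimated correlation. No list of this comparison kept its call with an estimated correlation, where 0.370 was the lowest of the 26 values. At the preset correlation 19 of 26 lists were called, and 15 by fry, which did not call astrocytes, pan-neuronal and synaptic genes, microglia, and hypoxia and glycolysis (adjusted p = 0.226, 0.0619, 0.0732 and 0.0820). With an estimated correlation 3 lists had an unadjusted p under the threshold.

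Among progenitor and glial lists, 11 of 25 radial glia genes rose and 1 fell (13 and 1 adjusted over the list alone), with camera adjusted p = 0.00506 and adjusted p = 0.445 with an estimated correlation. Pax6 rose 4.08-fold, although its wild-type counts were 962 in this table and 1150 in the other, and Nes rose by 1.62 ± 0.14. Of 15 genes of pyramidal intermediate progenitors 7 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.00137, adjusted p = 0.370 with an estimated correlation). Eomes, the usual marker of these cells, differed by 0.76 ± 0.42 and did not pass (adjusted p = 0.192). Of 18 genes of multipotent intermediate progenitors 10 rose and 2 fell (11 and 3 adjusted over the list alone), including Gsx2 (5.35-fold), with camera adjusted p = 0.0197 and adjusted p = 0.394 with an estimated correlation. The number that fell was 0 without ShhN IUE library 1 or 3 or wild-type library 1 or 2. Egfr differed by 0.41 ± 0.16 and did not pass (adjusted p = 0.0810). Of 25 oligodendrocyte lineage genes 12 rose and 2 fell (14 and 2 adjusted over the list alone), including Olig2 (1.84-fold) and Gpr17 (1.73 ± 0.20 on the log2 scale). Their camera adjusted p was 0.00899, and adjusted p = 0.445 with an estimated correlation. Pdgfra differed by 0.35 ± 0.13 and did not pass (adjusted p = 0.0689). Of 24 astrocyte genes 8 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0393, adjusted p = 0.630 with an estimated correlation). The astrocyte call was lost without ShhN IUE library 3 (adjusted p = 0.142) and without wild-type library 1 or 3 (adjusted p = 0.139 and 0.0987), and 4 genes rose without that ShhN IUE library and 3 without either of these wild-type libraries. Gfap rose 2.20-fold (adjusted p = 0.0480), a call lost without any 1 of the ShhN IUE libraries, without wild-type library 1 or 3 and with upper quartile scaling (adjusted p up to 0.145), and its log2 fold change of 1.14 was 1.73 without wild-type library 2.

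Among neuronal lists, 13 of 24 genes of the olfactory bulb interneuron lineage rose and 1, Six3, fell, also adjusted over the list alone (camera adjusted p = 0.000508, adjusted p = 0.445 with an estimated correlation). Of 18 striatal projection neuron genes 17 fell, also adjusted over the list alone, with a median of -3.02 and Zfp503 at -2.86 ± 0.25 (camera adjusted p = 1.22e-10, adjusted p = 0.370 with an estimated correlation). Six3 stands in both lists. Other lists share members too, such as Olig1 and Olig2 (multipotent intermediate progenitors and oligodendrocyte lineage) and Slc1a3 and Aldoc (radial glia and astrocytes). Notch1 and Hes1 stand in the radial glia and Notch pathway lists. Calls of lists that share genes are therefore not separate evidence. Of 16 genes of interneurons from the medial ganglionic eminence (MGE) 8 fell and 2 rose (9 and 2 adjusted over the list alone), with Maf at -1.35 ± 0.13 (camera adjusted p = 0.00506, adjusted p = 0.445 with an estimated correlation). Of 22 deep-layer pyramidal neuron genes 12 fell and 0 rose (12 and 1 adjusted over the list alone), with camera adjusted p = 0.00285 and adjusted p = 0.445 with an estimated correlation. Bcl11b fell by 0.98 on the log2 scale (SE 0.11), with 16139 wild-type counts in this table and 11734 in the other. Of 20 upper-layer genes 8 fell and 3 rose (9 and 4 adjusted over the list alone), and the set did not pass (adjusted p = 0.140). The number that rose was 1 without ShhN IUE library 1 or 2 or wild-type library 1 or 2, and 5 without ShhN IUE library 3. Of 24 pan-neuronal and synaptic genes 10 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0133, adjusted p = 0.595 with an estimated correlation). This call was lost without ShhN IUE library 3 (adjusted p = 0.0668) or wild-type library 1 (adjusted p = 0.0732), and without ShhN IUE library 3, 6 genes fell and 2 rose. Of 10 Cajal-Retzius cell genes 5 fell, also adjusted over the list alone, with Reln at -0.88 ± 0.13 (camera adjusted p = 0.00881, adjusted p = 0.445 with an estimated correlation), and 3 fell without ShhN IUE library 1.

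Among the other lists, 7 of 15 hypoxia and glycolysis genes rose (12 adjusted over the list alone), including Adm (2.24 ± 0.39), Vegfa (1.70 ± 0.34) and Hk2 (2.23 ± 0.45), with camera adjusted p = 0.00137 and adjusted p = 0.493 with an estimated correlation. The number was 4 without ShhN IUE library 1, 13 without ShhN IUE library 2 and 3 without wild-type library 3. The log2 fold change of Hk2 was 1.59 without ShhN IUE library 3. Of 15 interferon response genes 8 rose, also adjusted over the list alone (camera adjusted p = 0.000508, adjusted p = 0.445 with an estimated correlation), with Ifi44 at 2.55 ± 0.43, and 5 rose without ShhN IUE library 3 and 4 without wild-type library 3. Of 18 microglial genes 5 rose, also adjusted over the list alone (camera adjusted p = 0.00285, adjusted p = 0.493 with an estimated correlation). Without ShhN IUE library 1 and 3 this was 1 and 2, and without wild-type library 1, 2 and 3 it was 2, 8 and 2. Of 9 ependymal and choroid plexus genes tested 3 rose, also adjusted over the list alone, with Foxj1 at 2.59 ± 0.38 (camera adjusted p = 0.00949, adjusted p = 0.394 with an estimated correlation). This call was lost without ShhN IUE library 1 or 2 (adjusted p = 0.0540 and 0.0934) or wild-type library 1 (adjusted p = 0.139, 3 rose and 2 fell), and 6 rose and 1 fell without ShhN IUE library 3. Of 15 Notch pathway genes 7 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00949, adjusted p = 0.445 with an estimated correlation), and 4 rose without wild-type library 1 or 3. Of 16 WNT pathway genes 3 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0401, adjusted p = 0.445 with an estimated correlation). This call was lost without ShhN IUE library 1 or 2 (adjusted p = 0.0540 and 0.0934) or wild-type library 2 (adjusted p = 0.111), and 5 fell without ShhN IUE library 3. The lists of the BMP pathway (1 of 15 rose, 2 fell; 0 and 1 adjusted over the list alone), endothelium and mural cells (4 of 20 rose), meninges (1 of 16 fell), blood (1 of 7 fell) and immediate early genes (3 of 16 rose, 7 fell) did not pass, and the last 4 had the same numbers adjusted over the list alone. Without ShhN IUE library 3, 7 meningeal genes and 5 BMP pathway genes fell. Of endothelium and mural cells 1 gene rose without ShhN IUE library 1 or 3 or wild-type library 1 or 3. Of the 52 counts of the 26 lists in either direction, 26 moved by over 1.5 times without at least 1 library. The blood list had a median of -0.0014 and a mean of 0.09, with camera in the downward direction. The share of counts from mitochondrial genes and their nuclear copies was 1.99% ± 0.162 in ShhN IUE and 4.11% ± 0.2502 in wild type (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). The same wild-type libraries had 1.97% in the other table.

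The count of changed genes was 3251 without ShhN IUE library 1, against 5380 with all libraries. Of the genes tested, 11957 had agreeing wild-type counts, and 4003 of these changed. The authors' deposited table calls 1160 genes up and 1127 down, of which 1808 were also called here, in the same direction.

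In SmoM2 against wild-type cortex, 27 of 30 cell cycle genes, 15 of 23 genes of the olfactory bulb interneuron lineage and 8 of 18 SHH pathway targets rose. In the same comparison 16 of 18 striatal, 10 of 16 MGE interneuron and 14 of 22 deep-layer neuron genes fell. These 6 lists passed camera at its preset correlation, and none did with an estimated correlation (lowest adjusted p = 0.177). Ptch1 rose 6.98-fold, from 41.3 ± 10.6 to 288 ± 14.8 CPM (SD, n = 3), Gli1 rose 6.21-fold and Hhip 7.19-fold. Sp8 rose 7.38-fold and Dlx2 3.17-fold. Tac1 fell from 10.5 ± 1.06 to 0.355 ± 0.0960 CPM, and Eomes fell from 11.8 ± 1.74 to 4.32 ± 1.37 CPM. Among 16485 genes tested, 1581 rose and 1531 fell (edgeR quasi-likelihood test).

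The largest rises were Hba-a2, Rpl26 (log2 fold change 6.74), Itih3 (4.15), Myo7a (3.78), Gp1bb (3.47), Entpd2 (2.93), Fam107a (2.90) and Sp8 (2.88). Hba-a2, an alpha globin gene with a near-identical neighbour, had 2504 counts in SmoM2 and 3 in wild type, a ratio of 659 with a 95% counting interval of 225 to 3199, and its reads may have been divided with Hba-a1. Rpl26, a ribosomal protein gene (chromosome 11, 68901583 to 68906989), had 2970, 2239 and 2951 counts in SmoM2 and 17, 27 and 15 in wild type. Gp1bb had 301 wild-type counts in this table and 1626 in the other, and its call was lost without wild-type library 2 or 3 and with limma-voom (adjusted p up to 0.0880), with a log2 fold change of 2.07 without SmoM2 library 3. The largest falls were Zbed6 (-5.10), Tac1 (-4.87), Strip2 (-3.79), Rasgrp1 (-3.49), Col25a1 (-3.37), Nexn (-3.19), Dio2 (-3.14) and Lin28b (-3.09). Zbed6 overlaps Zc3h11a, and its wild-type counts were 24, 70 and 1506. Its call was lost without wild-type library 3, where its log2 fold change was -1.40, and also without any 1 of the SmoM2 libraries, with limma-voom and with the replicate block (adjusted p up to 0.273).

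Of 18 SHH pathway targets 8 rose and 2 fell (9 and 2 adjusted over the list alone), with Nkx2-2 at 2.64 ± 0.19 on the log2 scale (SE) and Gli2 at 0.99 ± 0.18. The camera adjusted p was 0.00405, and adjusted p = 0.391 with an estimated correlation. When any 1 library was left out, 1 target fell. Of 16 pathway components 3 rose and 2 fell (4 and 3 adjusted over the list alone), and the set did not pass (adjusted p = 0.254). Gli3 differed by -0.43 ± 0.15 (adjusted p = 0.0849). Of 30 cell cycle genes 27 rose (29 adjusted over the list alone), with a median of 1.22 and Mki67 at 1.56 ± 0.17 (camera adjusted p = 1.63e-16, adjusted p = 0.237 with an estimated correlation). At the preset correlation 16 of 26 lists were called, 17 by fry and 0 with an estimated correlation, where the lowest adjusted p was 0.177 and 5 lists had an unadjusted p under the threshold. Lists called by camera and not by fry were pan-neuronal and synaptic genes, microglia and interferon response (adjusted p = 0.0580 for each). Those called by fry and not by camera were SHH pathway components, pyramidal intermediate progenitors and blood, upward, and upper-layer neurons, downward (fry adjusted p = 0.0109, 0.0251, 0.0496 and 0.0240).

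Of 26 oligodendrocyte lineage genes 14 rose (15 adjusted over the list alone), with Olig2 up 2.46-fold and Cnp at 1.64 ± 0.10 (camera adjusted p = 8.77e-06, adjusted p = 0.177 with an estimated correlation), and 9 rose without SmoM2 library 1 or 2. Pdgfra rose 1.41-fold (adjusted p = 0.0255), a call lost without any 1 of the SmoM2 libraries and without wild-type library 1 or 3 (adjusted p up to 0.0963). Of 25 radial glia genes 12 rose and 3 fell (15 and 4 adjusted over the list alone), with Pax6 up 2.14-fold and Slc1a3 at 1.26 ± 0.13 (camera adjusted p = 0.000300, adjusted p = 0.288 with an estimated correlation), and 1 fell without SmoM2 library 2 or 3. Of 24 astrocyte genes 9 rose (13 rose and 1 fell adjusted over the list alone), with Ntsr2 at 2.31 ± 0.22 (camera adjusted p = 6.84e-05, adjusted p = 0.391 with an estimated correlation), and 5 rose without SmoM2 library 1. Gfap rose 2.47-fold (adjusted p = 0.0417), a call lost without any 1 of the SmoM2 libraries and without wild-type library 1 or 3, and with the replicate block (adjusted p up to 0.134), and its log2 fold change of 1.31 was 1.91 without wild-type library 2. Of 18 genes of multipotent intermediate progenitors 9 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00194, adjusted p = 0.311 with an estimated correlation). Egfr rose 1.75-fold and Gsx2 2.94-fold. Of 15 genes of pyramidal intermediate progenitors 4 rose and 2, Eomes and Sstr2, fell (6 and 2 adjusted over the list alone), and the set did not pass (adjusted p = 0.0891). The number that rose was 7 without wild-type library 1.

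Of 23 olfactory bulb interneuron lineage genes 15 rose and 2 fell (15 and 3 adjusted over the list alone), with a median of 1.34 (camera adjusted p = 1.09e-05, adjusted p = 0.256 with an estimated correlation). Of 18 striatal projection neuron genes 16 fell (17 adjusted over the list alone), with a median of -2.41 (camera adjusted p = 5.79e-13, adjusted p = 0.177 with an estimated correlation). Of 16 MGE interneuron genes 10 fell (11 adjusted over the list alone), with Sst at -2.58 ± 0.21 (camera adjusted p = 1.09e-05, adjusted p = 0.177 with an estimated correlation). Of 22 deep-layer genes 14 fell and 1 rose (16 and 1 adjusted over the list alone), with Tbr1 at -1.002 ± 0.0993 and Bcl11b at -1.12 ± 0.12 (camera adjusted p = 3.56e-08, adjusted p = 0.237 with an estimated correlation). Of 10 Cajal-Retzius cell genes 8 fell (9 adjusted over the list alone), with Reln at -1.24 ± 0.12 (camera adjusted p = 1.06e-06, adjusted p = 0.177 with an estimated correlation), and 5 fell without SmoM2 library 3. Of 24 pan-neuronal and synaptic genes 7 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.457 with an estimated correlation). This call was lost without wild-type library 1 (adjusted p = 0.0820), and 4 fell without SmoM2 library 1 or 3. Of 20 upper-layer genes 8 fell and 4 rose, also adjusted over the list alone, and the set did not pass (adjusted p = 0.178), with 2 rising without SmoM2 library 3.

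Of 18 microglial genes 3 rose (5 adjusted over the list alone), with camera adjusted p = 0.000219 and adjusted p = 0.391 with an estimated correlation. It was 10 without wild-type library 2 and 1 without any other 1 of the libraries. Of 16 interferon response genes 1, Ifit2, rose, also adjusted over the list alone (camera adjusted p = 0.000365, adjusted p = 0.391 with an estimated correlation), and 2 and 6 rose without wild-type library 1 and 2. Of 13 ependymal and choroid plexus genes 6 rose, also adjusted over the list alone (camera adjusted p = 0.00678, adjusted p = 0.391 with an estimated correlation), and 2 rose without any 1 of the SmoM2 libraries. Of 15 Notch pathway genes 5 rose and 2 fell (7 and 2 adjusted over the list alone), with camera adjusted p = 0.00515 and adjusted p = 0.288 with an estimated correlation. The lists of hypoxia and glycolysis (1 of 15 rose), WNT pathway (1 of 16 fell), endothelium and mural cells (0 of 20) and meninges (1 of 16 fell) did not pass and had the same numbers adjusted over the list alone. The BMP pathway (2 of 15 fell, 1 adjusted over the list alone), blood (2 of 7 rose and 1 fell, 5 and 1 adjusted over the list alone) and immediate early genes (2 of 16 rose and 4 fell, 4 and 6 adjusted over the list alone) did not pass either. Without wild-type library 2, 7 genes of endothelium and mural cells rose, and without wild-type library 3, 2 genes of hypoxia and glycolysis fell. Of the BMP pathway 0 fell without SmoM2 library 2 or 3. Of the 52 counts of the 26 lists in either direction, 23 moved by over 1.5 times without at least 1 library. The WNT pathway had a median of 0.04 and a mean of -0.03, with camera in the upward direction, and the BMP pathway had 0.07 and -0.01, with camera downward and fry upward. Mitochondrial genes and their nuclear copies took 1.84% ± 0.355 of counts in SmoM2 and 1.97% ± 0.140 in wild type (SD, n = 3, two-sided exact permutation p = 0.6).

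**Figure D2:**
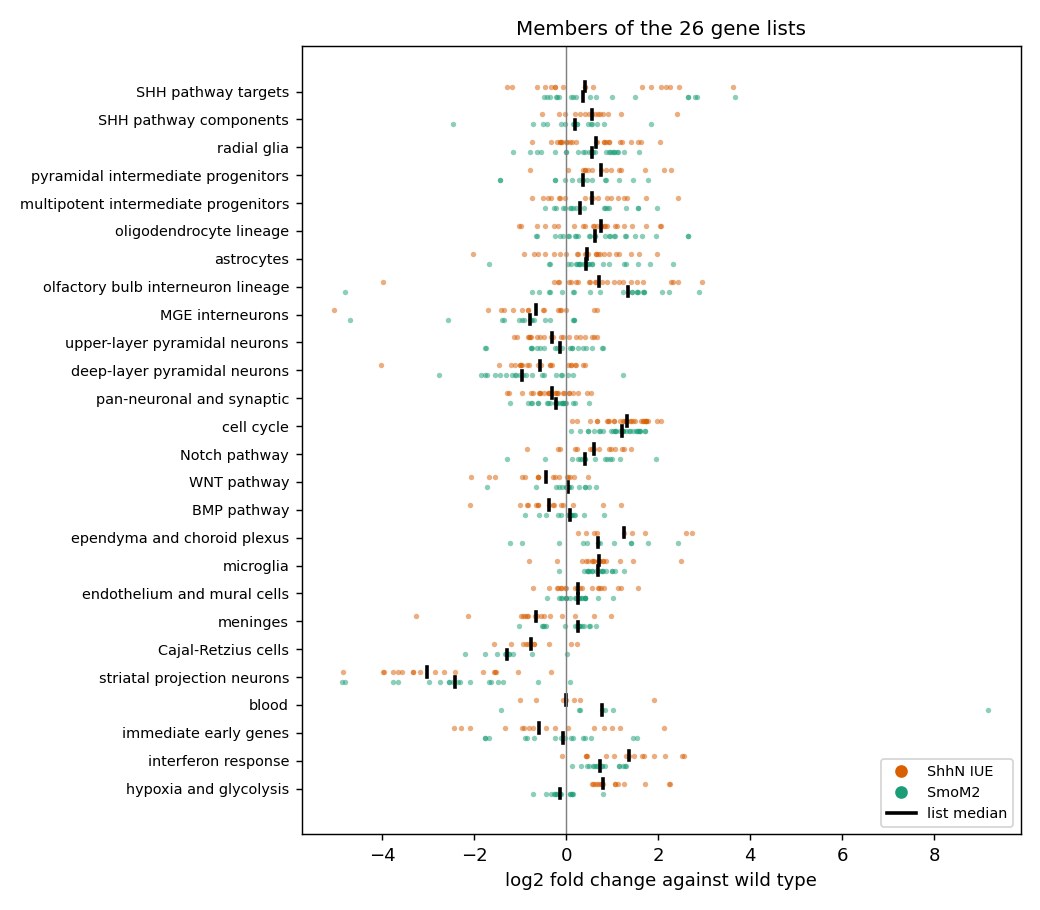
Log2 fold change against wild type of each tested member (points) of the 26 gene lists in ShhN IUE and SmoM2, with the list median as a black line. The cell cycle medians are 1.32 and 1.22, and the striatal projection neuron medians are -3.02 and -2.41.

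The count of changed genes was 1727, 1694 and 1334 without SmoM2 library 1, 2 and 3, against 3112 with all libraries. Of the genes tested, 12237 had agreeing wild-type counts, and 2345 of these changed. The authors' deposited table calls 715 genes up and 728 down, of which 1122 were also called here, in the same direction.

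Many genes passed the test in both interventions. Of 16006 genes tested in both, 1067 rose in both and 1009 fell in both, and 16 changed in opposite directions. Independent lists of the same lengths would share 243 and 262 genes. Sp8, Dlx2, Gli1 and Ptch1 were among the genes that rose in both, and Tac1, Rasgrp1 and Nexn among those that fell in both. Both comparisons use the same wild-type libraries, which alone makes their fold changes resemble each other. Over 11857 genes with agreeing wild-type counts the fold changes had a correlation across genes of 0.726, where genes are not independent replicates, against a mean of 0.511 in 20 simulations of unchanged groups with shared controls. Their covariance was 0.360 against 0.0509 simulated, a difference of 0.309, and 77.4% against 66.7% of genes had the same sign. Over these 11857 genes 1602 changed in the same direction in both. The simulations gave 0.1 on average, but unchanged groups leave few genes to call in either comparison. That number therefore cannot show how much of the overlap the shared controls add. The 3 wild-type libraries were too few to divide, so part of the overlap may come from the shared controls. It was 1253, 1248 and 985 genes without SmoM2 library 1, 2 and 3, against 2076.

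**Figure D3:**
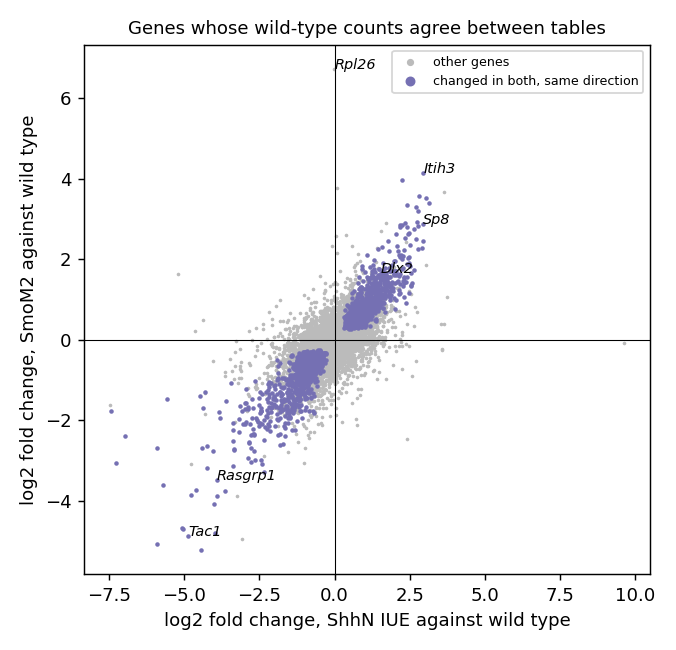
Log2 fold change against wild type in ShhN IUE (horizontal) and in SmoM2 (vertical) for genes whose wild-type counts agree between the tables; each point is a gene, coloured where it changed in the same direction in both. The correlation across genes is 0.726, against 0.511 in simulated unchanged groups with the same controls.

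**Figure D4:**
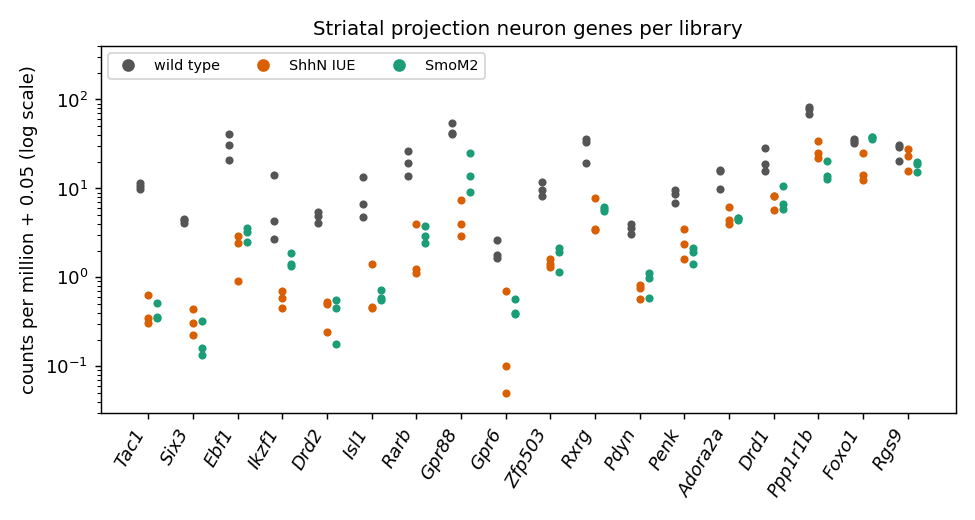
CPM of the library total plus 0.05, on a log axis, of the 18 striatal projection neuron genes; points are the 3 libraries of each group. Wild-type and ShhN IUE values come from 1 deposited table and SmoM2 values from the other. Wild-type counts agree between them for 12 of the 18 genes. For the rest, the distance between wild type and SmoM2 also reflects the different counting. Tac1 was at 10.8 CPM in wild type, 0.371 in ShhN IUE and 0.355 in SmoM2 (TMM-scaled means).

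The interventions were compared with each other in a joint fit of 12349 genes with agreeing wild-type counts, a set of genes settled only after the data were examined, where the plan had been to give values side by side if the tables' wild-type counts differed. Eomes and Neurog2, markers of pyramidal intermediate progenitors, were lower in SmoM2 than in ShhN IUE, by 4.50-fold and 2.76-fold. The log2 fold change of Eomes was -1.52 without ShhN IUE library 2, against -2.17 with all libraries. Of 11 genes of hypoxia and glycolysis 7 were lower (camera adjusted p = 0.000282, adjusted p = 0.829 with an estimated correlation). Gli2, Gli3 and Gsx2 were lower by 1.83, 1.56 and 1.89-fold, and Smo was higher by 1.86-fold. Ptch1, Gli1 and Hhip differed by 0.65 ± 0.31, 0.19 ± 0.32 and 0.60 ± 0.49 on the log2 scale and did not pass (adjusted p = 0.173, 0.720 and 0.429). In all, 1043 genes were higher and 997 lower in SmoM2 (edgeR quasi-likelihood test). Some of these may reflect different counting of the 2 groups, which agreeing wild-type counts do not exclude.

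By the naming rule, the genes highest in SmoM2 relative to ShhN IUE were Rpl29 (log2 fold change 6.81), Rpl26 (6.67), Rpl10-ps3 (4.86), Myo7a (3.79), Hfm1 (2.86), Amy1 (2.30), Tacr1 (2.28) and Rpl21 (2.20). The lowest were Xist (-9.71), Shh (-4.87), Rps12-ps3 (-3.25), Aif1 (-2.77), Ddit4 (-2.28), Eomes (-2.17), Hk2 (-2.11) and Tpt1 (-2.07). Counts of ribosomal protein genes, pseudogenes and Tpt1 are uncertain where near-identical copies share their reads. The search for copies reported below found no counted copy of Rpl26, and it did not cover Tpt1 or the pseudogenes. Xist rests on ShhN IUE library 2, with 56724 counts against 39 and 33 in the others and a log2 fold change of -0.59 without it. Its call was lost without that library or any 1 of the SmoM2 libraries. It was also lost with limma-voom, with the replicate block and in a fit of the 6 libraries alone (adjusted p up to 0.474). ShhN IUE library 2 had 1 count of the Y-linked gene Ddx3y, against 1333, 1792 and 1560 in SmoM2. That is the pattern of a female sample, so the Xist difference goes with the sex of 1 library. Rpl29 had 10, 14 and 1768 counts in wild type, and its call was lost without ShhN IUE library 1 or 2 or any 1 of the SmoM2 libraries (adjusted p up to 0.0857). The log2 fold changes of Shh and Hk2 were -2.89 and -1.48 without ShhN IUE library 3. The calls of Gsx2 and Gli3 were also lost without ShhN IUE library 1 or without SmoM2 library 2, and that of Gsx2 without SmoM2 library 1 (adjusted p up to 0.0692 and 0.0647). Dlx2, Olig2, Egfr, Pdgfra and Gfap differed by 0.06 ± 0.12, 0.41 ± 0.16, 0.42 ± 0.13, 0.14 ± 0.11 and 0.16 ± 0.33 and did not pass.

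At the preset correlation 3 of 26 lists were called, 5 by fry and 0 with an estimated correlation, where 2 lists had an unadjusted p under the threshold. Camera called 6 lists without ShhN IUE library 3 and 5 without SmoM2 library 3. Of the 11 hypoxia and glycolysis genes 10 were lower adjusted over the list alone, with a median of -1.004 and Adm at -2.95 ± 0.35, and, adjusted over all genes, 4 and 3 were lower without SmoM2 library 2 and 3. Of 12 genes of pyramidal intermediate progenitors 6 were lower (7 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 0.00268, adjusted p = 0.455 with an estimated correlation). Without ShhN IUE library 1 or 3 it was 3, and without SmoM2 library 1 or 2 it was 2. Of 10 Cajal-Retzius cell genes 3 were lower (7 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 0.00268, adjusted p = 0.455 with an estimated correlation). It was 0 without ShhN IUE library 1 or SmoM2 library 2, and 1 without SmoM2 library 1 or 3. The cell cycle list (1 of 27 lower, also adjusted over the list alone, adjusted p = 0.107) and the striatal list (1 of 12 higher, also adjusted over the list alone, adjusted p = 0.583) did not pass, and 3 striatal genes were higher without ShhN IUE library 3. The remaining 21 lists did not pass camera either, with adjusted p from 0.101 to 0.993, though fry called the WNT pathway upward and SHH pathway components downward (fry adjusted p = 0.0173 and 0.0480), and, where no other number is given, the same counts adjusted over the list alone. These were SHH pathway targets (0 of 16 higher and 3 lower), SHH pathway components (1 of 12 higher and 4 lower), radial glia (2 of 19 higher and 4 lower), multipotent intermediate progenitors (1 of 16 higher and 2 lower, 3 and 2 adjusted over the list alone) and oligodendrocyte lineage (1 of 20 higher and 2 lower). They included astrocytes (2 of 18 higher and 0 lower), olfactory bulb interneuron lineage (2 of 21 higher and 4 lower, 2 and 6 adjusted over the list alone), MGE interneurons (0 of 12 higher and 4 lower, 1 and 4 adjusted over the list alone), upper-layer pyramidal neurons (3 of 14 higher and 3 lower) and deep-layer pyramidal neurons (2 of 16 higher and 5 lower). Others were pan-neuronal and synaptic (3 of 16 higher and 1 lower, 4 and 1 adjusted over the list alone), Notch pathway (0 of 13 higher and 3 lower, 0 and 4 adjusted over the list alone), WNT pathway (4 of 12 higher and 1 lower, 7 and 2 adjusted over the list alone), BMP pathway (2 of 15 higher and 1 lower, 2 and 2 adjusted over the list alone) and ependyma and choroid plexus (0 of 13 higher and 3 lower). Also tested were microglia (0 of 16 higher and 1 lower), endothelium and mural cells (0 of 17 higher and 2 lower), meninges (0 of 15 higher and 0 lower), blood (1 of 6 higher and 0 lower, 3 and 1 adjusted over the list alone) and immediate early genes (2 of 14 higher and 3 lower). The last was interferon response (0 of 14 higher and 2 lower, 0 and 3 adjusted over the list alone). The multipotent progenitor list had a median of -0.04 with camera upward, the microglial list a median of 0.01 with a mean of -0.08, and the upper-layer list camera downward and fry upward. Without ShhN IUE library 3, 6 SHH pathway targets were higher and 2 lower in SmoM2, and 10 meningeal genes were higher. Of the 52 counts of the 26 lists in either direction, 40 moved by over 1.5 times without at least 1 library. The count of genes that differed was 936 without ShhN IUE library 1, and 1125, 834 and 962 without SmoM2 library 1, 2 and 3, against 2040.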

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

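The interventions differed from each other in the joint fit, a departure from the planned design whose set of genes was settled after the data were examined, in 3 lists and in many genes named in the text. On the log2 scale, SmoM2 minus ShhN IUE, the medians were -0.53 for pyramidal intermediate progenitors, -0.52 for Cajal-Retzius cells and -1.004 for hypoxia and glycolysis. With an estimated correlation none of these lists passed (adjusted p = 0.455, 0.455 and 0.829). The genes named in the text include some outside the naming rule, such as Dbx1, Sox1, Rpl39, mt-Nd1 and mt-Nd5, picked after the data were examined. Those higher in SmoM2 by the edgeR test of the difference were Amy1 (2.30), Dbx1 (2.97), Hfm1 (2.86), Myo7a (3.79), Rpl10-ps3 (4.86), Rpl21 (2.20), Rpl26 (6.67), Rpl29 (6.81), Rpl39 (1.69), Smo (0.90), Sox1 (0.85), Tacr1 (2.28), mt-Nd1 (0.98) and mt-Nd5 (0.93). Those lower in SmoM2 were Adm (-2.95), Aif1 (-2.77), Ddit4 (-2.28), Eomes (-2.17), Foxj1 (-1.20), Gli2 (-0.87), Gli3 (-0.65), Gsx2 (-0.92), Hk2 (-2.11), Ifi44 (-1.42), Nes (-0.64), Neurog2 (-1.47), Rps12-ps3 (-3.25), Shh (-4.87), Sst (-0.90), Sstr2 (-0.65), Tpt1 (-2.07), Vegfa (-1.99) and Xist (-9.71). Without any 1 of the SmoM2 libraries the calls of Foxj1, Ifi44 and Sst were lost, as were those of Foxj1 without ShhN IUE library 1 or 2, of Ifi44 without 3 and of Sst without 1 (adjusted p up to 0.105, 0.0888 and 0.0710). The Xist difference rests on ShhN IUE library 2, which has the counts of a female sample. Of the tests reported here, those of the wild-type tables, striatal tissue, loss of neurons and exchange of reads were chosen after the result was seen. So were those of strain variants, shares of 2-fold genes and handling.

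Genes of striatal projection neurons were lower in both interventions (adjusted p = 0.370 in ShhN IUE and 0.177 in SmoM2 with an estimated correlation, which no list passed). The tables argue against scaling between libraries, since the highest list median over 3 scalings and both comparisons was -2.40. Members with agreeing wild-type counts had medians no higher than -2.33, so the differing tables do not account for it. Striatal tissue in the wild-type dissections and loss of these neurons in both interventions cannot be told apart. At least 88.9% of the 18 fell in each comparison, which restates the pattern, and the median between the interventions of 0.16 separates neither, because both comparisons share the wild-type libraries. Striatal tissue, if present, could also lower genes of other lists that striatal cells express. Whether the falls of MGE interneuron, deep-layer and synaptic genes are separate from the striatal fall was not tested.

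Single ribosomal protein genes changed many-fold. By a test chosen after the result was seen, low counts do not account for it as a whole. At 20 CPM or more, 10 of 67 ribosomal protein genes were at least 2-fold apart in ShhN IUE, against 493 of 8363 other genes. In SmoM2 it was 7 of 72 against 217 of 8332 (two-sided Fisher's exact p = 0.00600 and 0.00295, over genes, which are not independent replicates). The spread of their fold changes there was 1.46, 2.43 and 3.56 times that of other genes in ShhN IUE, SmoM2 and SmoM2 against ShhN IUE. The 95% intervals over resampled genes were 1.07 to 1.83, 1.04 to 3.77 and 1.47 to 5.25. In ShhN IUE the spread missed the bound set beforehand to exclude low counts, so that planned test cannot decide. Exchange of reads between near-identical copies cannot be told apart from other causes: the median offset in the copies was as low as -0.0122 of the change in the gene, and in ShhN IUE it was 0.732 for Rps2 but -0.686 for Rpl15 and -0.367 for Rpl39, whose copies moved with the gene. Copies were found for 57.1% of the 14 called changes of at least 2-fold, which count Rps28 in both comparisons, in a search changed once after its first form had found 35.7%, too few to decide. Strain variants stay open as well on this mixed background, with 2 ribosomal protein genes at least 8-fold apart between wild-type libraries no sequence to examine, and no biological explanation tested.

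Of 15 hypoxia and glycolysis genes 7 rose in ShhN IUE (camera adjusted p = 0.00137, adjusted p = 0.493 with an estimated correlation, and 0.0820 by fry). Their mean log2(CPM + 1) was 6.25, 5.55 and 6.76 in ShhN IUE and 5.43, 5.29 and 5.09 in wild-type libraries 1, 2 and 3. A single library does not account for it, since the lowest list median without one ShhN IUE library was 0.61, and neither does scaling, with a lowest median of 0.80. Handling of the tissue cannot be told apart from ShhN IUE itself, because no label records it per group. The list median of -0.14 in SmoM2 against wild type is what either would give.

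With 10 splits of 3 against 3, the share of splits with a result as large cannot fall under 0.1, so these splits are too few to judge chance. ShhN IUE against wild type gave 5380 genes and the highest other split 12, SmoM2 against wild type gave 3112 and 1, and SmoM2 against ShhN IUE, on the 6 libraries alone, gave 2468 and 1. In each, 1 of the 10 splits, the real one, gave as many genes.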

How the results depend on the processing

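The restriction to agreeing wild-type counts and the other tolerances were chosen after seeing the data. Counts of changed genes stayed within 1.5 times under the other scalings, filters and tools, with 5139 to 5775 genes for ShhN IUE against wild type, 2840 to 3584 for SmoM2 against wild type and 1832 to 2514 for SmoM2 against ShhN IUE. No scaling moved the median log2 fold change of all genes by more than 0.1. With a 2-fold minimum they were 1877, 1135 and 497 for SmoM2 against ShhN IUE, and 685 genes changed in both interventions, by the stricter construction. Without single libraries the ranges were 3251 to 4624, 1334 to 3010, 834 to 2336 and 985 to 1882 in the same order, with fewer samples in each fit. The lists called ranged from 17 to 20, 15 to 19 and 3 to 6. With an estimated correlation 0 lists were called in each comparison, and for SmoM2 against ShhN IUE fry and the replicate block each called 5. Same-numbered libraries did not all deviate together, with correlations of 0.278, -0.322 and -0.0632 for ShhN IUE and wild type. For SmoM2 and wild type they were -0.121, -0.169 and 0.0554. Not every sample correlated best with its own number. Deviations from a mean of 3 libraries constrain each other, so these values cannot exclude that numbers mark shared litters. The replicate block gave 3962, 2468 and 1499 genes, and 1526 in both interventions. The genes with agreeing wild-type counts gave 4146 and 2548 when fitted alone, and tolerances of 0.05 and 0.2 gave 1735 and 2426 differences between the interventions. Of the named genes called, 88 of 105, 85 of 97 and 41 of 80 kept their call under every alternative in which they were tested, and 0 reversed. Some alternatives did not test every named gene. Genes that had not passed and turned sign, with their range without single libraries, were Igf2 in ShhN IUE (-2.43 to 0.39), Igf2 in SmoM2 (-0.99 to 0.55; 0.0149 with limma-voom) and Lum in SmoM2 (-1.05 to 0.58; 0.20 with limma-voom and 0.0097 with the replicate block). Between the interventions they were Dlx2 (-0.0080 to 0.19), Gli1 (-0.0399 to 0.78, with -0.0227 without ShhN IUE library 2), Ctss (-0.39 to 0.0783) and Gfap (-0.0226 to 0.29). The cause was not tested. At these depths the edgeR test recovered 46.5% of simulated 2-fold changes for ShhN IUE against wild type, so changes of this size can be missed. A part of its calls is expected to be wrong, with 11.2% false in the simulation. The simulation changed 200 genes, where the data gave 5380 calls. Both shares depend on the number of changed genes, so neither carries over to these calls as a value.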

Other observations

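Genes annotated to cell differentiation in the spinal cord rose in SmoM2, a term found by testing all terms, whose genes named here were chosen after their values were seen. Of 36 tested genes with this term 18 rose, against 3.66 by chance (one-sided Fisher's exact test over genes, which are not independent replicates, adjusted p = 4.43e-07 over 3909 terms). They included Nkx2-2 (log2 fold change 2.64), Nkx6-2 (3.66), Sox1 (1.77) and Gsx1 (1.97). Dbx1 had 167 counts in SmoM2 and 1 in wild type, a ratio of 132 with a 95% counting interval of 23.4 to 5240. Genes annotated to chromosome segregation rose in both interventions, 74 of 225 in ShhN IUE (37.0 by chance) and 62 of 228 in SmoM2 (23.2 by chance). Genes annotated to the synaptic membrane fell in both as well, 82 of 218 in ShhN IUE (38.7 by chance) and 64 of 221 in SmoM2 (21.7 by chance). The test of terms does not allow for genes that change together, and no term was tested with an estimated correlation.

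Mitochondrial and sex-linked genes were also looked at after the data were examined. Of 13 mitochondrial genes tested in ShhN IUE, 6 had agreeing wild-type counts, and these 6 fell (edgeR adjusted p up to 0.00582, no set test run), with mt-Nd5 at -1.51 ± 0.14 and mt-Nd1 at -1.41 ± 0.15 on the log2 scale. In SmoM2 3 of the 6 fell, with these at -0.56 ± 0.09 and -0.40 ± 0.08. Transcripts of the Y chromosome were near 0 in 2 libraries. Ddx3y had 1 count in ShhN IUE library 2, where Xist had 56724, and 2 counts in wild-type library 3, where Xist had 37. In the other 7 libraries Ddx3y had 740 to 1792 counts. ShhN IUE library 2 thus has the pattern of a female sample, and wild-type library 3 that of neither sex. Sex was not balanced between the groups.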
